A study of Mus musculus with 8 samples.

How the data were processed

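Germ cells of mouse testes at postnatal day 14 expressing a Dazl-GFP-V5 fusion were lysed without crosslinking, RNA was precipitated, and Cy3-labelled RNA was hybridised to one-colour arrays with 43379 non-control spots for 41174 probes, per the labels' protocols and the file headers. The 8 arrays form 4 groups of 2: input total RNA, a mock precipitate with normal mouse IgG, a V5 precipitate and a GFP precipitate. Groups were taken from the titles, sources and antibodies of the samples. Per the file headers, the input and IgG arrays were scanned as one slide and the V5 and GFP arrays as another.

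The deposited intensity values were made with Agilent Feature Extraction 9.1.3.1, per the file headers, which subtracted background, corrected trends over the slide and put surrogate values where a spot was not above background; no scaling between arrays was applied. The deposited table of the whole series holds signal values that the authors normalized to the median in GeneSifter and averaged over 3 groups, input, V5 and GFP, per the file's comment lines. It has 41529 entries for 31853 identifiers, and the IgG arrays are not among its conditions. Only its group means were used, and its 6 other columns of values were not used here.

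For each array log2 of the processed signal was taken and the 75th percentile of all non-control spots subtracted. Spots marked as outliers were left out and spots of 1 probe averaged. Probes well above background on both arrays of at least 1 group were kept, and the probe with the highest mean signal stood for each gene name, which gave 17580 genes, of which 5939 had more than 1 kept probe. Of all probes 22951 matched a RefSeq accession of assembly GRCm38.p6, used for symbols and for which chromosome a gene lies on. With 2 arrays per group, their number limits the precision.

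Group means were fitted over the 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, 4 residual and 2.41 prior degrees of freedom), and 6 comparisons were tested, each two-sided with Benjamini-Hochberg adjustment over all genes at 0.05. Every adjusted p in the text comes from limma, for genes from its moderated test and for lists from its camera test. SE is that of the moderated test. Where a gene was not above background on any array of the dimmer group, a lower bound of its fold change was computed against that group's background level.

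The 22 gene lists were fixed before the data were examined: reported Dazl-bound transcripts, spermatogonia, meiotic prophase, late spermatocyte and spermatid, piRNA pathway, pluripotency, Polycomb, apoptosis, RNA-binding and translation factors, cell cycle, ribosomal proteins, histones, oxidative phosphorylation, nuclear long noncoding RNAs, proteasome, endoplasmic reticulum, and markers of Sertoli, Leydig, myoid, leukocyte, endothelial and erythroid cells. The 21 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. With a correlation estimated per list 0 lists passed camera in any of the 6 comparisons, and 3, 4, 0, 1, 2 and 5 had an unadjusted p under 0.05 in the order of the comparisons V5 and GFP against IgG, IgG against input, V5 and GFP against input, and V5 against GFP. Camera with an estimated correlation also rests on the 4 residual degrees of freedom, so its loss of calls is not due to correlation alone. For Polycomb genes in V5 against IgG, with an estimated correlation of -0.02, camera's unadjusted p went from 0.000497 to 0.0163. The fry test, which asks only whether a list's genes move on balance one way, called 19, 18, 14, 17, 20 and 13 lists. Lists share members: 6 of the 10 measured Dazl-bound transcripts, 6 of 20 spermatogonial genes and 4 of 23 pluripotency genes are in another list. The input RNA also held markers of other cell types. All measured markers, 21 Sertoli, 13 Leydig, 15 myoid, 19 leukocyte, 13 endothelial and 5 erythroid, lay above background on both input arrays. Measured markers had already passed the background filter in at least 1 group, which favours this result. Of the listed markers, 13 of 15 Leydig and 5 of 10 erythroid ones were measured.

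Named genes were chosen by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest fold changes against IgG, and 5 each way in the other comparisons, among genes past the threshold whose arrays do not overlap and which lie above background on both arrays of the brighter group, without accessions and clone names. Genes with only a bound were taken by their fitted fold change, which gives them no rank. It adds Dazl, Pabpc1 and the reported Dazl-bound transcripts everywhere, and up to 4 members of each list with the smallest p, of which a part is printed. One gene that the rule names is not reported here. The genes named for the overlaps were chosen after their values were seen.

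The procedure was tested on simulated data for V5 against IgG, with 17580 genes of which 200 were changed, 50 for each size. Of these limma recovered 0% at a log2 change of 0.25, 18% at 0.5, 86% at 1 and 100% at 2, and 2.86% of calls were false. A list shifted by 0.5 was called, with 0 others. The simulated genes varied independently of each other, while the estimated correlation within the ribosomal protein list was 0.437. These rates therefore need not hold for correlated lists, or where many more genes change. For the overlap of the antibodies, 100 simulations of unchanged groups against the same IgG arrays were drawn, and the same draws gave the overlaps of genes above both controls.

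Alternatives fixed before the data were examined were quantile normalization, scaling to the median of probes above background on all arrays, scaling to the spike-in probes, normexp background correction with an offset of 50, no filter on background, only probes above background on all arrays, the mean of all probes of a gene, eBayes with trend and robust, replicate number as a block, only the compared groups in the fit, estimated correlations, leaving out each array, and the authors' means. Of 10 spike-in probes 7 lay above background on all arrays and were used. A background subtraction with an offset of 50 in place of normexp, and leaving out both arrays of conflicting descriptions, were chosen after seeing the data. GC content and probe sequences were not analysed here.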

Results

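Germ cells of mouse testes at postnatal day 14 expressed Dazl, an RNA-binding protein of germ cells, as a fusion with the tags GFP and V5. Per the labels' protocols, RNA was precipitated from their lysates without crosslinking, and Cy3-labelled RNA was hybridised to one-colour arrays. The input RNA also held markers of other cell types of the testis, among them all 21 measured Sertoli markers. The 8 arrays form 4 groups of 2: input total RNA, a mock precipitate with normal mouse IgG, a precipitate with an antibody against V5, and a precipitate with an antibody against GFP. Each array held 43379 non-control spots, of which 57.2% to 62.3% lay well above background, and 0 spots were saturated on any of the 8 arrays. The 75th percentile of the signal lay between 857 and 1115. Across probes, which are not independent replicates, arrays of a group correlated at Pearson r = 0.9919 for input, 0.9898 for IgG, 0.9929 for V5 and 0.991 for GFP.

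The labels hold 3 conflicts. The series text names an antibody against PABP1 where the samples name one against GFP; the samples' name was used, and all values given for GFP rest on it. The descriptions of input replicate 2 and V5 replicate 1 name the other kind of RNA than their titles, sources and antibodies do. Their correlations of 0.9919 and 0.9929 with the other array of their group fit the titles, which were used. Input and IgG arrays lay on one slide, and V5 and GFP arrays on another. How much a difference between the slides adds to a difference of V5 or GFP from IgG or input therefore cannot be told apart from the groups. IgG against input and V5 against GFP lie within a slide. The labels do not say that replicates are separate animals, so each p measures the spread between these samples, which may be technical. That spread is pooled over all 4 groups. The median absolute log2 difference between replicates was 0.159 for IgG, 0.077 for input, 0.092 for V5 and 0.085 for GFP. The SE of comparisons with IgG may therefore be too small. Values below are log2 fold changes ± SE from limma with 2 arrays per group, each array scaled to its 75th percentile, over 17580 genes.

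The first comparison asks which transcripts came down with V5-tagged Dazl above the IgG mock. Dazl's own transcript was 1.97-fold higher (0.98 ± 0.15, adjusted p = 0.00404). Higher as well were the transcription factor Dmrt1 (1.63 ± 0.081, 3.1-fold, adjusted p = 0.00072) and the receptor Kit (1.21 ± 0.079, 2.31-fold). So were Sycp3, of the synaptonemal complex (1.45 ± 0.20, 2.73-fold, adjusted p = 0.00321), and the RNA-binding protein Elavl2 (1.75 ± 0.12, 3.38-fold). Lower were Espn of Sertoli cells (-0.62 ± 0.084) and C1qb of macrophages (-0.65 ± 0.097).

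Of 10 measured transcripts that earlier work reported as bound by Dazl, 7 were higher with V5 than with IgG, and also 7 adjusted over the list alone (median 0.63, camera adjusted p = 7.12e-05, and adjusted p = 0.262 with an estimated correlation). Besides Dazl and Sycp3 these were Tex19 (0.76 ± 0.086), Sdad1 (0.84 ± 0.094), Tbpl1 (0.85 ± 0.089), the germ cell helicase Ddx4 (0.46 ± 0.15, adjusted p = 0.0419) and Grsf1 (0.38 ± 0.092). The call of Ddx4 ended without V5 replicate 1, V5 replicate 2 or IgG replicate 2 (0.46, 0.46 and 0.21), and that of Grsf1 without V5 replicate 1 or IgG replicate 2 (0.32 each). Crisp2 (0.49 ± 0.20, adjusted p = 0.068; past the threshold without IgG replicate 1, at 0.72), Cdc25a (-0.057 ± 0.076) and Cdc25c (0.065 ± 0.085) did not pass, and in both Cdc25 genes 1 of 2 probes had the opposite sign. Of 20 spermatogonial genes 11 were higher and 3 lower, also 11 and 3 adjusted over the list alone (median 0.40, camera adjusted p = 0.000322, and adjusted p = 0.29 with an estimated correlation). Lin28, named Lin28a in RefSeq (1.09 ± 0.078), and Foxo1 (0.73 ± 0.070) were among the higher ones. RNA-binding and translation factors gave 29 higher and 7 lower of 51, and the same numbers adjusted over the list alone (median 0.39, camera adjusted p = 5.52e-07, and adjusted p = 0.262 with an estimated correlation), with Elavl1 at 1.10 ± 0.088. Pabpc1, the cytoplasmic poly(A)-binding protein, did not pass (-0.23 ± 0.12, adjusted p = 0.153), though it did without IgG replicate 2 (-0.38).

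Of 45 cell cycle genes 20 were higher and 6 lower, among the higher E2f5 (1.10 ± 0.080), Ccnd1 (1.02 ± 0.11) and Cdk2 (0.87 ± 0.092), and the list passed camera (median 0.16, adjusted p = 7.12e-05, and adjusted p = 0.174 with an estimated correlation). Polycomb genes gave 15 higher and 6 lower of 32 (median 0.13, adjusted p = 0.00209, and adjusted p = 0.174 with an estimated correlation), with Rnf2 at 1.34 ± 0.15 and Pcgf5 at 1.09 ± 0.088. Genes of the endoplasmic reticulum gave 12 higher and 7 lower of 36 (median 0.048, adjusted p = 0.00358, and adjusted p = 0.353 with an estimated correlation), with the translocon subunit Ssr1 at 1.17 ± 0.084. Meiotic prophase genes gave 8 higher and 6 lower of 27 (median 0.068, adjusted p = 0.0219, and adjusted p = 0.397 with an estimated correlation), with Tex12 at 1.40 ± 0.18. piRNA pathway genes gave 6 higher and 3 lower of 20 (median 0.069, adjusted p = 0.016, and adjusted p = 0.353 with an estimated correlation), with Fkbp6 at 0.60 ± 0.081 and Prmt5 at -0.44 ± 0.075. Without IgG replicate 2 the meiotic list no longer passed, with a median of -0.032. With normexp background correction the endoplasmic reticulum (median -0.048), meiotic prophase (0.099) and piRNA pathway (0.01) lists no longer passed. Adjusted over the list alone, the counts higher and lower were 20 and 6 for the cell cycle, 15 and 7 for Polycomb genes, 12 and 7 for the endoplasmic reticulum, 8 and 5 for meiotic prophase, and 5 and 2 for the piRNA pathway.

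Among somatic lists, 15 of 21 Sertoli markers were lower with V5 than with IgG (median -0.35, camera adjusted p = 0.00658, and adjusted p = 0.262 with an estimated correlation), but their median turned to 0.017 when arrays were scaled to spike-in RNA. Lower too were 14 of 15 peritubular myoid markers (median -0.42, adjusted p = 0.00425, and adjusted p = 0.353 with an estimated correlation), with Tagln at -0.57 ± 0.065. The same held for 16 of 19 leukocyte markers (median -0.46, adjusted p = 0.00562, and adjusted p = 0.353 with an estimated correlation). Lower were also 12 of 13 endothelial markers (median -0.47, adjusted p = 0.00562, and adjusted p = 0.397 with an estimated correlation), with Vwf at -0.56 ± 0.072. With spike-in scaling these 3 medians were -0.056, -0.095 and -0.11. Ribosomal protein genes gave 43 lower and 2 higher of 79 (median -0.25, adjusted p = 0.00562, and adjusted p = 0.619 with an estimated correlation), but their median turned to 0.12 with spike-in scaling. Oxidative phosphorylation genes gave 40 lower and 4 higher of 72 (median -0.29, adjusted p = 0.00658, and adjusted p = 0.564 with an estimated correlation), but their median turned to 0.077 with spike-in scaling. That scaling shifts all genes of an array alike and took the median over all genes from -0.206 to 0.159. The Sertoli, ribosomal protein and oxidative phosphorylation medians lay below it in both settings, but with spike-in scaling these lists no longer passed camera. Without IgG replicate 1 the Sertoli, ribosomal protein and oxidative phosphorylation lists no longer passed, at medians of -0.39, -0.18 and -0.21. Adjusted over the list alone, 15 Sertoli, 14 myoid, 16 leukocyte and 13 endothelial markers were lower, as were 43 ribosomal protein genes and 41 oxidative phosphorylation genes.

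The other 7 lists did not pass with V5: late spermatocyte and spermatid genes (median -0.37, adjusted p = 0.115), pluripotency genes (-0.14, adjusted p = 0.0746), apoptosis genes (-0.17, adjusted p = 0.413), histones (-0.23, adjusted p = 0.181), proteasome genes (-0.17, adjusted p = 0.643), Leydig markers (-0.29, adjusted p = 0.0687) and erythroid markers (-0.51, adjusted p = 0.0949). For pluripotency and apoptosis genes camera's direction was upward. Camera compares a list with the other genes, and these 2 medians, though below 0, lay above the median of -0.206 over all genes. Pluripotency genes passed without V5 replicate 1 (-0.039) or IgG replicate 2 (0.003), histones without IgG replicate 2 (-0.35) and Leydig markers without V5 replicate 2 (-0.33). Single members still changed, as the germ cell and embryonic gene Dppa3 (1.58 ± 0.093), the apoptosis gene Pmaip1 (1.59 ± 0.092) and the spermatid protein gene Tnp2 (-0.98 ± 0.19). Of the list named nuclear long noncoding RNAs 4 were measured, too few for a list test, and where they lie in the cell was not measured. H19 was lower (-0.48 ± 0.086), and Kcnq1ot1 was not well above background in either group. Gas5 (-0.17 ± 0.066) and Malat1 (-0.52 ± 0.22) did not pass, though both did without IgG replicate 2 (-0.22 and -0.80).

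The highest fold changes over IgG among transcripts measured in both groups were those of Ube2v2 (2.04 ± 0.26), Taf7 (2.02 ± 0.14), Nxt2 (1.87 ± 0.15), C1d (1.83 ± 0.16), Vbp1 (1.79 ± 0.22), Rnf138 (1.78 ± 0.19), Spbc25, the kinetochore gene Spc25 (1.78 ± 0.084), and Elavl2. Pawr (at least 4.74-fold higher) and Nap1l5 (at least 1.73-fold) were not well above background with IgG, so their bounds give no rank. The same holds for genes lower with V5 and not well above background there, Olfr975 (at least 2.22-fold lower), F11 (at least 3.72-fold), Kirrel1, Pklr, Slc18a2, Mmp28, Yipf7 and Insm2. Olfr611 was above background on 1 of 2 arrays with V5 (-3.02 ± 0.68). Among these genes, the calls of Pawr, Nap1l5, Olfr611, F11 and Kirrel1 ended when 1 of the V5 or IgG arrays was left out. In all, limma called 2938 genes higher, 420 of them at least 2-fold, and 7095 lower, 783 of them at least 2-fold, around a median of -0.21 over all genes. With spike-in scaling that median was 0.16 and 87.2% of calls were higher in place of 29.3%. With only the V5 and IgG arrays in the fit limma called 7348 genes. The 10033 calls fell to 6035 without V5 replicate 1 and to 6682 without V5 replicate 2, and without both arrays of conflicting descriptions 1249 remained in number. Without these 2 arrays the calls of Dazl (0.92), Sycp3 (1.44), Espn (-0.65), C1qb (-0.61), Ddx4, Grsf1, Tex12, Fkbp6, Prmt5, Tagln, Vwf, H19, Ube2v2, Nap1l5, Vbp1, F11 and Kirrel1 ended, and pluripotency genes passed. With normexp background correction limma called 0 genes, with 3688 at an unadjusted p under 0.05. The normexp fit placed the background at -391 on V5 replicate 2, against -13.7 on V5 replicate 1. With local background subtracted and the same offset of 50, chosen after seeing the data, limma called 11309 genes.

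**Figure D1:**
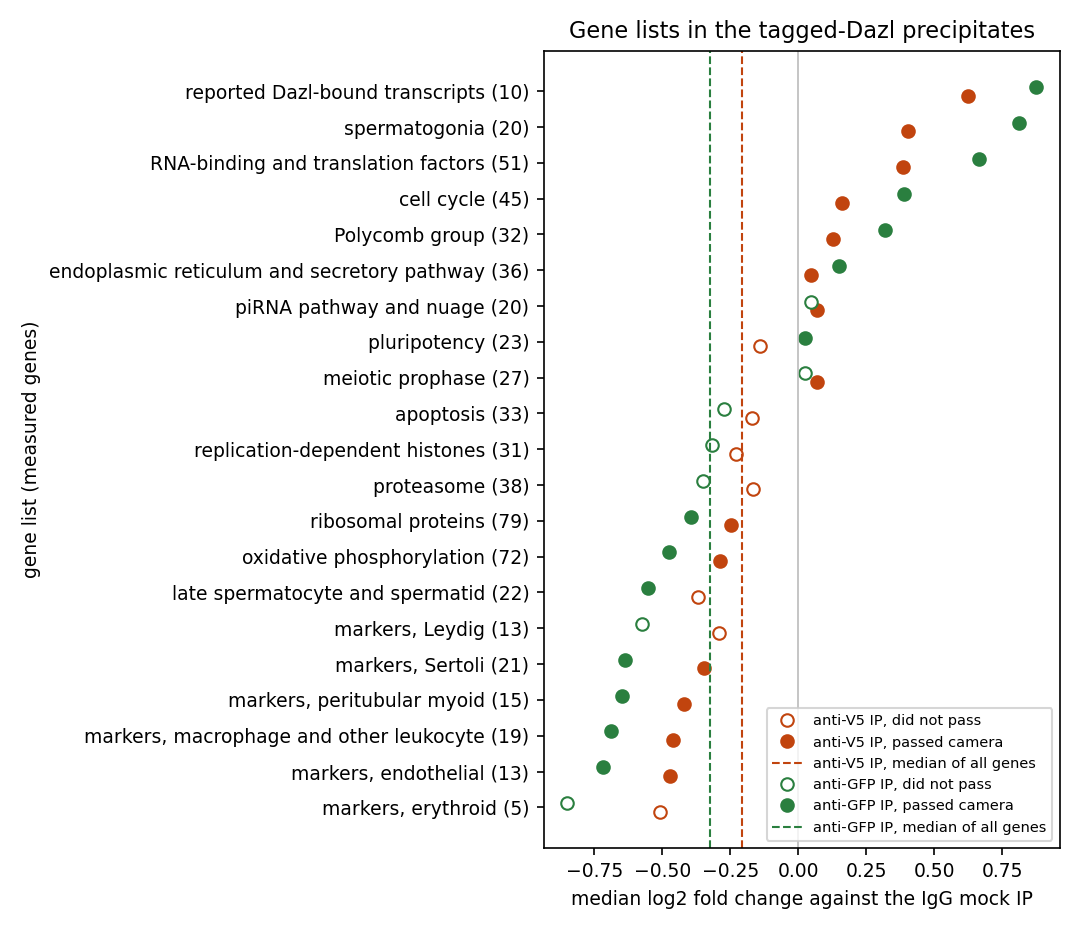
Median log2 fold change of each gene list against the IgG mock precipitate (x axis) for the V5 and GFP precipitates, with filled points where camera's adjusted p passed and dashed lines at the median of all genes. Reported Dazl-bound transcripts sit highest (0.63 and 0.88). With spike-in scaling the V5 medians of Sertoli, ribosomal protein and oxidative phosphorylation genes turn positive, as does that of all genes (0.159).

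The second comparison puts the same question with the antibody against GFP. Dazl's transcript was 2.81-fold higher than with IgG (1.49 ± 0.15, adjusted p = 0.000369). Dmrt1 was 5.3-fold higher (2.41 ± 0.081, adjusted p = 7.43e-05), Kit 3.46-fold (1.79 ± 0.079) and Lin28 3.43-fold (1.78 ± 0.078). Sycp3 was 3.15-fold higher (1.66 ± 0.20) and the synaptonemal complex gene Tex12 3.75-fold (1.91 ± 0.18). Espn (-0.82 ± 0.084) and C1qb (-1.03 ± 0.097) were again lower.

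Of the 10 reported Dazl-bound transcripts 8 were higher with GFP, and 8 adjusted over the list alone (median 0.88, camera adjusted p = 0.000114, and adjusted p = 0.242 with an estimated correlation). They included Tex19 (1.19 ± 0.086), Tbpl1 (1.13 ± 0.089), Grsf1 (0.62 ± 0.092), Ddx4 (0.45 ± 0.15), Cdc25a (0.38 ± 0.076) and Sdad1 (1.35 ± 0.094), of which 1 of 2 probes had the opposite sign. Ddx4 no longer passed without either GFP array or IgG replicate 2 (0.39, 0.51 and 0.20). Crisp2 (0.041 ± 0.20) and Cdc25c (-0.068 ± 0.085) did not pass. Spermatogonial genes gave 13 higher and 4 lower of 20 (median 0.81, adjusted p = 2.19e-05, and adjusted p = 0.232 with an estimated correlation), with Foxo1 at 1.33 ± 0.070. RNA-binding and translation factors gave 31 higher and 9 lower of 51 (median 0.66, adjusted p = 7.97e-08, and adjusted p = 0.231 with an estimated correlation), with Elavl2 at 2.13 ± 0.12. Pabpc1 was lower (-0.36 ± 0.12, adjusted p = 0.034), a sign that the spike-in scaling turns (0.11), and it no longer passed without either GFP array or IgG replicate 1 (-0.38, -0.34 and -0.21). Cell cycle genes gave 26 higher and 12 lower of 45 (median 0.39, adjusted p = 2.19e-05, and adjusted p = 0.16 with an estimated correlation), with Cdk2 at 1.57 ± 0.092. Polycomb genes gave 16 higher and 8 lower of 32 (median 0.32, adjusted p = 0.000995, and adjusted p = 0.16 with an estimated correlation), with Pcgf5 at 1.51 ± 0.088. Endoplasmic reticulum genes gave 18 higher and 7 lower of 36 (median 0.15, adjusted p = 0.000687, and adjusted p = 0.349 with an estimated correlation), with Spcs2 at 1.78 ± 0.089. Pluripotency genes gave 8 higher and 6 lower of 23 (median 0.026, adjusted p = 0.0153, and adjusted p = 0.318 with an estimated correlation), with Dppa3 at 2.17 ± 0.093 and Klf5 at 1.73 ± 0.097, but the list no longer passed without IgG replicate 1 (-0.081). Adjusted over the list alone, the counts were 13 and 4, 31 and 9, 26 and 12, 16 and 8, 17 and 6, and 8 and 6, in the order of these lists from spermatogonia to pluripotency.

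Sertoli markers were lower with GFP for 19 of 21 genes (median -0.64, adjusted p = 0.00176, and adjusted p = 0.184 with an estimated correlation). So were myoid markers for 14 of 15 (median -0.65, adjusted p = 0.00471, and adjusted p = 0.349 with an estimated correlation). Leukocyte markers were lower for 17 of 19 (median -0.69, adjusted p = 0.00471, and adjusted p = 0.349 with an estimated correlation), and endothelial markers for 13 of 13 (median -0.72, adjusted p = 0.00549, and adjusted p = 0.418 with an estimated correlation). With spike-in scaling these medians were -0.17, -0.18, -0.22 and -0.25. Late spermatocyte and spermatid genes gave 18 lower of 22 (median -0.55, adjusted p = 0.0383, and adjusted p = 0.418 with an estimated correlation), with the transition protein gene Tnp1 at -1.15 ± 0.16, but the list no longer passed without IgG replicate 1 (-0.63). Ribosomal protein genes gave 63 lower and 3 higher of 79 (median -0.40, adjusted p = 0.000751, and adjusted p = 0.526 with an estimated correlation), but their median turned to 0.077 with spike-in scaling. Oxidative phosphorylation genes gave 59 lower and 4 higher of 72 (median -0.47, adjusted p = 0.00094, and adjusted p = 0.451 with an estimated correlation), with a median of -0.003 under spike-in scaling. That scaling took the median over all genes from -0.325 to 0.146. The ribosomal protein and oxidative phosphorylation medians lay below it in both settings, but with spike-in scaling these lists no longer passed camera. The late spermatocyte and spermatid list also did not pass with normexp background correction (-0.307) or only probes above background on all arrays (-0.52). Adjusted over the list alone, 19 Sertoli, 14 myoid, 17 leukocyte, 13 endothelial, 18 late spermatocyte and spermatid, 65 ribosomal protein and 59 oxidative phosphorylation genes were lower. Meiotic prophase genes (median 0.023, adjusted p = 0.0553), piRNA pathway genes (0.045, adjusted p = 0.0669), apoptosis genes (-0.27, adjusted p = 0.571), histones (-0.32, adjusted p = 0.165), proteasome genes (-0.35, adjusted p = 0.237), Leydig markers (-0.58, adjusted p = 0.06) and erythroid markers (-0.85, adjusted p = 0.108) did not pass, and for apoptosis genes camera's direction was upward. Meiotic prophase genes passed without GFP replicate 1 (0.068), GFP replicate 2 (-0.025) or IgG replicate 1 (0.15). So did piRNA pathway genes without GFP replicate 2 (0.13) or IgG replicate 1 (0.11), erythroid markers without GFP replicate 1 (-0.83) and Leydig markers without GFP replicate 2 (-0.68). Of the 4 measured noncoding RNAs Malat1 (-0.91 ± 0.22), Gas5 (-0.40 ± 0.066) and H19 (-0.39 ± 0.086) were lower and Kcnq1ot1 was not well above background in either group, and spike-in scaling turns the sign of Gas5 (0.070) and H19 (0.081).

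The highest fold changes with GFP were those of Taf7 (2.67 ± 0.14), Nxt2 (2.60 ± 0.15), Hccs (2.52 ± 0.11), Dck (2.43 ± 0.091), Dmrt1, Cetn2 (2.35 ± 0.088), Ube2v2 (2.34 ± 0.26, with 1 of 3 probes of opposite sign), Spbc25 (2.29 ± 0.084), Pggt1b (2.27 ± 0.23, above background on 1 of 2 IgG arrays) and Taf9b (2.27 ± 0.20). Lower, not well above background with GFP and so without rank, were Lalba (at least 4.4-fold lower), Trpv6 (at least 3.69-fold, with no call when any GFP or IgG array was left out), Klk15 (at least 2.4-fold), Olfr1134 (at least 4.53-fold), Olfr353, Insm2, Pla2g2f, Marveld3 and Sox14. Ifnab was above background on 1 of 2 arrays with GFP (-3.23 ± 0.29). Calls by limma numbered 3804 higher, 1197 of them at least 2-fold, and 9161 lower, 1173 of them at least 2-fold, around a median of -0.33 over all genes. With spike-in scaling that median was 0.15 and 75.7% of calls were higher in place of 29.3%. With normexp background correction the 12965 calls fell to 3219. The calls of Ddx4 and Pabpc1 ended without both arrays of conflicting descriptions, and meiotic prophase genes passed.

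The precipitates labelled V5 and GFP shared many transcripts. Among the genes higher than with IgG, 2859 were shared by V5 and GFP, Dazl, Dmrt1, Kit, Sycp3 and Taf7 among them. Independent lists of these sizes would share 636. Simulated unchanged groups against the same IgG arrays shared 0. With no changed gene they give few calls to share, so this 0 is no measure of what shared controls add. Lower in both were 6829 genes, where independent lists would share 3697, while 3 genes were higher with V5 and lower with GFP and 4 the reverse. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.92 and Spearman rho = 0.919, against 0.498 and 0.463 in the simulated unchanged groups. Both share the 2 IgG arrays, and V5 and GFP lie together on another slide than IgG. Part of the excess may therefore come from these controls or from the slide. Without both arrays of conflicting descriptions the overlap was 647 genes, without V5 replicate 1 it was 1886, and with normexp background correction it was 0, since limma then called 0 genes with V5 and 3688 at an unadjusted p under 0.05.

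**Figure D2:**
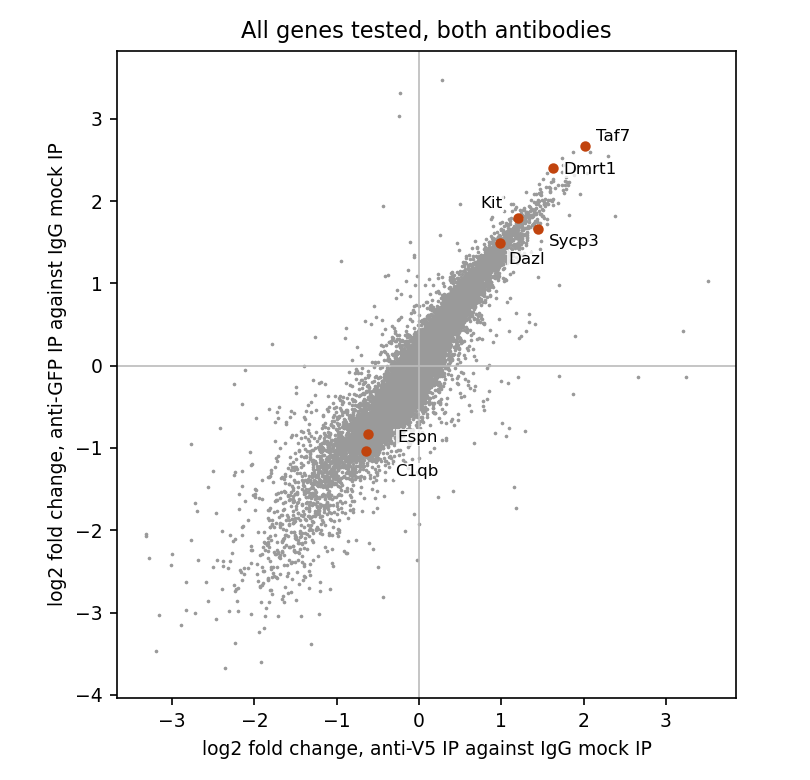
Log2 fold changes of 17580 genes against the IgG mock precipitate, V5 on the x axis and GFP on the y axis, 1 grey point per gene, with 7 genes named in the text in orange. The points lie along a rising line (Pearson r = 0.92), and both axes share the IgG arrays.

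The mock precipitate shows what IgG recovered from the input RNA, within a slide. Lower than in the input were the meiotic genes Sycp1, 71.1-fold (-6.15 ± 0.19, adjusted p = 6.32e-06), Sycp3, 30.5-fold (-4.93 ± 0.20), and Hormad1, 30.3-fold (-4.92 ± 0.24). The kinase gene Rock1 was 85-fold lower (-6.41 ± 0.24, above background on 1 of 2 IgG arrays), and the ciliary gene Ift74 at least 38.9-fold. Col3a1 was 4.79-fold (2.26 ± 0.062) and Col1a1 4.52-fold higher (2.18 ± 0.061), though 10 of 15 myoid markers, among which both are counted, were lower and that list did not pass (median -0.52, adjusted p = 0.0787). Dazl itself was 4.22-fold lower (-2.08 ± 0.15, adjusted p = 3.61e-05), and the Polycomb genes Ezh2 (-1.73 ± 0.097) and Cbx2 (1.86 ± 0.077) went opposite ways.

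Furthest above the input stood Usp19 (3.58 ± 0.088), Tnxb (3.34 ± 0.14), Ppp1r10 (3.24 ± 0.094), Vars2 (3.19 ± 0.086) and Cdc42bpb (3.12 ± 0.095), and Kntc2, the kinetochore gene Ndc80, was at least 36.6-fold lower. Of the 10 reported Dazl-bound transcripts 7 were lower and 2 higher than in the input, and the same adjusted over the list alone (median -0.80, camera adjusted p = 0.0481, and adjusted p = 0.847 with an estimated correlation). Ddx4 (-1.61 ± 0.15), Crisp2 (-2.07 ± 0.20), Grsf1 (-1.27 ± 0.092), Cdc25c (-0.34 ± 0.085) and Sdad1 (-0.33 ± 0.094) were lower, Tex19 was higher (1.35 ± 0.086), Cdc25a was higher (0.40 ± 0.076) but turned lower with spike-in scaling, and Tbpl1 did not pass (-0.14 ± 0.089). Sdad1 no longer passed without input replicate 1 (-0.28), nor Cdc25c without input replicate 2 (-0.28). Proteasome genes gave 26 lower and 8 higher of 38 (median -0.76, adjusted p = 7.05e-05), histones 20 lower and 5 higher of 31 (median -0.60, adjusted p = 0.0056), meiotic prophase genes 16 lower and 7 higher of 27 (median -0.49, adjusted p = 0.0179) and oxidative phosphorylation genes 27 lower and 12 higher of 72 (median -0.071, adjusted p = 0.0438). For each of these 4 lists the adjusted p was 0.847 with an estimated correlation, and the counts were the same adjusted over the list alone. The proteasome gene Psmd12 (-2.05 ± 0.072) and Hist1h2ai (-1.21 ± 0.089) were among them, and Pabpc1 was lower (-0.54 ± 0.12).

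The other 16 lists did not pass between IgG and input, with adjusted p from 0.0583 for piRNA pathway genes to 0.858 for apoptosis genes. Among them spermatogonial genes had a median of 0.29, endothelial markers 0.42 and myoid markers -0.52, and with spike-in scaling the medians of the first 2 turned to -0.50 and -0.37. For cell cycle, ribosomal protein, endoplasmic reticulum and erythroid genes camera's direction was downward. Their medians were positive but lay below that of all genes. In number, limma called 7720 genes higher, 2669 of them at least 2-fold, and 5158 lower, 2196 of them at least 2-fold, around a median of 0.22 over all genes. With spike-in scaling that median was -0.57 and 18.1% of calls were higher in place of 59.9%. The 12878 calls fell to 6272 with normexp background correction, and the 5 lists became 3 without input replicate 2 or without IgG replicate 2, those of Dazl-bound transcripts (-0.80 and -0.78) and oxidative phosphorylation (-0.048 and -0.038) no longer passing. These 2 lists did not pass without both arrays of conflicting descriptions either, and the calls of Cdc25a (0.33), Cdc25c (-0.28) and Sdad1 (-0.39) ended.

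Against the input, Sycp1 and Rock1 were low with V5 and with GFP too. Sycp1 was 76-fold lower with V5 (-6.25 ± 0.19) and 88.8-fold with GFP (-6.47 ± 0.19), and Rock1 80.9-fold and 82-fold. Dazl stayed below its level in the input, at -1.10 ± 0.15 with V5 (adjusted p = 0.000682) and -0.58 ± 0.15 with GFP (adjusted p = 0.0112), where it no longer passed without GFP replicate 2 (-0.49) or input replicate 2 (-0.54). Above the input stood Tex19 (2.11 ± 0.086 and 2.54 ± 0.086), Lin28 (1.84 ± 0.078 and 2.53 ± 0.078), Kit (1.38 ± 0.079 and 1.96 ± 0.079) and Cbx2 (2.02 ± 0.077 and 2.38 ± 0.077). Rhox5, a Sertoli marker, was below it (-1.79 ± 0.084 and -2.12 ± 0.084).

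Of the 10 reported Dazl-bound transcripts 4 were higher and 6 lower than in the input with either antibody, and the same adjusted over the list alone (medians -0.58 and -0.49, camera adjusted p = 0.53 and 0.809). Higher were Tex19, Sdad1 (0.51 ± 0.094 and 1.01 ± 0.094, with 1 of 2 probes of opposite sign), Tbpl1 (0.71 ± 0.089 and 0.99 ± 0.089) and Cdc25a (0.34 ± 0.076 and 0.78 ± 0.076), whose sign with V5 turns under spike-in scaling (-0.083). Sdad1 turned lower when all its probes were averaged (-0.76 and -0.60). Lower were Dazl, Sycp3 (-3.49 ± 0.20 and -3.27 ± 0.20), Ddx4 (-1.15 ± 0.15 and -1.16 ± 0.15), Crisp2 (-1.57 ± 0.20 and -2.02 ± 0.20), Grsf1 (-0.89 ± 0.092 and -0.65 ± 0.092) and Cdc25c (-0.27 ± 0.085 and -0.41 ± 0.085, with V5 no longer past the threshold without V5 replicate 1 or input replicate 2), as was Pabpc1 (-0.77 ± 0.12 and -0.90 ± 0.12). The highest among genes measured in both groups were Usp19 (8.71-fold), Ppp1r10 (7.8-fold) and Col6a3 (6.84-fold) with V5, and Zdhhc18 (7.18-fold), Usp19 (7.13-fold) and the centromere gene Cenpa (7.1-fold) with GFP. Not well above background in the input, and so without rank, were Sv2a (at least 1.73-fold with V5), Pygo1 (at least 3.41-fold with V5 and 4.56-fold with GFP) and Dlx2 (at least 7.68-fold with GFP). Lower, and not well above background with either antibody, were Ift74 (at least 46.6-fold and 42.8-fold), Kntc2 (at least 43.8-fold and 40.2-fold) and Cep290 (at least 10.1-fold and 9.32-fold).

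**Figure D3:**
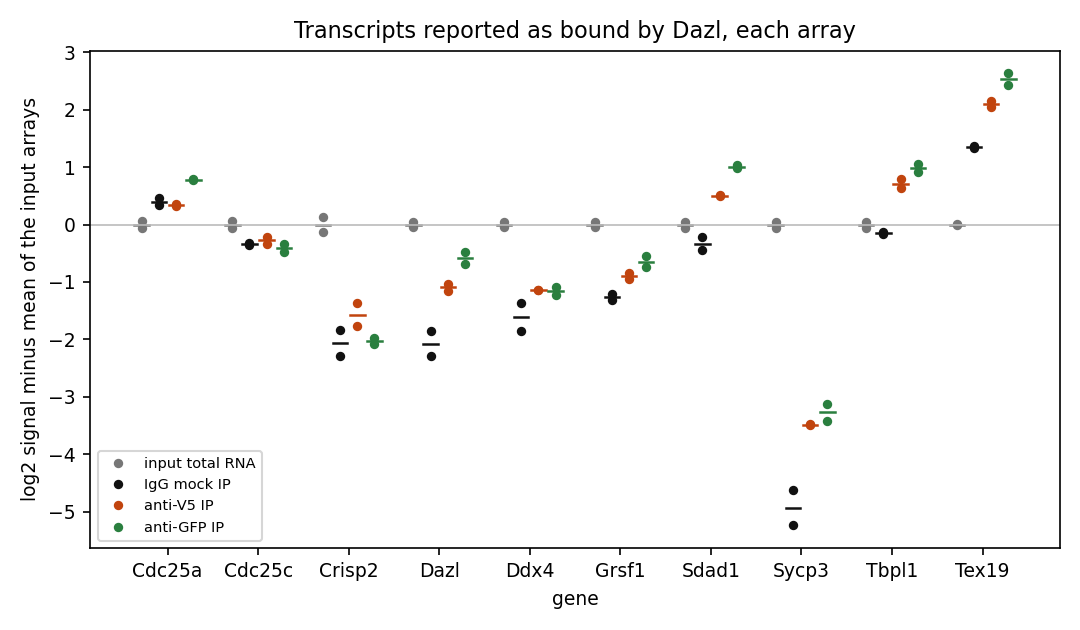
Log2 signal of the 10 measured transcripts reported as bound by Dazl, each array a point and each group's mean a bar, relative to the mean of the input arrays (y axis), by gene (x axis). Dazl sits lowest with IgG (-2.08) and higher with V5 (-1.10) and GFP (-0.58), and Tex19 lies above the input in all 3 precipitates.

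Of 20 spermatogonial genes 12 with V5 and 14 with GFP were higher than in the input (medians 0.77 and 1.09, camera adjusted p = 0.0266 and 0.00209, and adjusted p = 0.536 and 0.383 with an estimated correlation), with Bcl6b at 1.49 ± 0.061 and 1.86 ± 0.061. Another 4 and 3 were lower. Of 32 Polycomb genes 18 and 22 were higher (medians 0.52 and 0.59, adjusted p = 0.0112 and 0.00154, and adjusted p = 0.536 and 0.21 with an estimated correlation). With spike-in scaling the spermatogonial medians were 0.35 and 0.78 and the Polycomb medians 0.098 and 0.27. Lower were 27 and 29 of 38 proteasome genes (medians -0.81 and -0.86, adjusted p = 3.42e-05 and 1.45e-05, and adjusted p = 0.536 and 0.383 with an estimated correlation), with Psmd12 at -2.06 ± 0.072 and -2.21 ± 0.072. Lower too were 50 and 54 of 72 oxidative phosphorylation genes (medians -0.40 and -0.57, adjusted p = 9.21e-05 and 7.07e-06, and adjusted p = 0.581 and 0.411 with an estimated correlation), with Ndufs4 at -1.48 ± 0.087 and -1.80 ± 0.087. Histones were lower for 23 and 24 of 31 genes (medians -0.85 and -0.97, adjusted p = 0.00459 and 0.00301, and adjusted p = 0.536 and 0.411 with an estimated correlation). Late spermatocyte and spermatid genes were lower for 15 of 22 with each antibody (medians -0.46 and -0.65, adjusted p = 0.023 and 0.00662, and adjusted p = 0.536 and 0.411 with an estimated correlation). With V5 this list (-0.02) and Polycomb genes (0.557) no longer passed under normexp background correction. The spermatogonial list did not pass with V5 when only probes above background on all arrays were used (0.712).

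Ribosomal protein genes were lower for 30 and 45 of 79 (medians -0.14 and -0.30, adjusted p = 0.0327 and 0.00154, and adjusted p = 0.774 and 0.614 with an estimated correlation), with Rpl4 at -1.80 ± 0.079 and -2.04 ± 0.079. With V5 that list no longer passed without V5 replicate 2 (-0.13) or input replicate 2 (-0.11). Among somatic markers, 13 and 16 of 21 Sertoli genes were lower (medians -0.35 and -0.64, adjusted p = 0.0266 and 0.00127, and adjusted p = 0.536 and 0.21 with an estimated correlation). Myoid markers were lower for 12 of 15 with each antibody (medians -0.92 and -1.12, adjusted p = 0.023 and 0.0163, and adjusted p = 0.536 and 0.411 with an estimated correlation), though the collagen Col3a1 was higher (2.06 ± 0.062 and 2.05 ± 0.062). Leukocyte markers were lower for 15 and 17 of 19 (medians -0.72 and -0.69, adjusted p = 0.00274 and 0.000706, and adjusted p = 0.536 and 0.383 with an estimated correlation). The counts of these 10 lists were the same adjusted over the list alone, except for 17 Polycomb genes with V5, 14 late spermatocyte and spermatid genes with GFP, and 29 and 42 ribosomal protein genes. The other 11 lists did not pass with either antibody, with adjusted p from 0.201 to 0.693 for V5 and from 0.0538 to 0.809 for GFP. With GFP, cell cycle genes passed without GFP replicate 1 (0.33) or GFP replicate 2 (0.30), RNA-binding and translation factors without GFP replicate 2 (0.26) and erythroid markers without GFP replicate 1 (-0.94).

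With V5, limma called 6620 genes higher than input, 1794 of them at least 2-fold, and 6251 lower, 2410 of them at least 2-fold, around a median of 0.005 over all genes. With spike-in scaling that median was -0.42 and 26.8% of calls were higher in place of 51.4%. With GFP there were 6356 higher, 1980 of them at least 2-fold, and 6873 lower, 2882 of them at least 2-fold, around a median of -0.059. With spike-in scaling it was -0.38 and 31.1% of calls were higher in place of 48%. Normexp background correction left 5250 calls of 12871 with V5 and 5697 of 13229 with GFP. With V5 the calls of Sdad1 (0.46), Cdc25a (0.29), Cdc25c (-0.15) and the ribosomal protein list (-0.13) ended without both arrays of conflicting descriptions. With GFP those of Dazl (-0.54) and Cdc25c (-0.34) ended, and RNA-binding and cell cycle lists passed.

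Above both controls stood 1493 genes with V5 and 2410 with GFP, where independent lists would share 1106 and 1375. Simulated unchanged groups shared 0.02 and 0 on average. With no changed gene they are no measure of what the shared arrays add. Both comparisons use the same V5 or GFP arrays and cross the slides, so part of the excess may come from either. Higher than IgG and input with both antibodies were 1472 genes, among them Lin28, Kit, Tex19, Tbpl1, Dppa3 and Cpeb1, a regulator of poly(A) tails. Dazl was not among them, being higher than IgG and lower than input. Without both arrays of conflicting descriptions 389 genes stood above both controls with V5. Normexp background correction gave 862 with GFP, and 0 with V5, since limma then called 0 genes between V5 and IgG and 3688 at an unadjusted p under 0.05.

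The last comparison sets V5 against GFP within a slide, 2 antibodies against tags on 1 protein if the samples' name for the second, and not the series text's PABP1, is right. Lower with V5 were Dmrt1 (-0.78 ± 0.081, 1.71-fold, adjusted p = 0.0262), Lin28 (-0.68 ± 0.078), Foxo1 (-0.60 ± 0.070) and the DNA methyltransferase gene Dnmt3b (-0.57 ± 0.072). Higher with V5 were the Sertoli cell genes Inhbb (0.31 ± 0.063, 1.24-fold, adjusted p = 0.035) and Dhh (0.29 ± 0.072). Dazl itself did not pass (-0.51 ± 0.15, adjusted p = 0.0637), nor did Pabpc1 (0.13 ± 0.12).

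Lower with V5 were 9 of 20 spermatogonial genes (median -0.41, camera adjusted p = 6e-07, and adjusted p = 0.175 with an estimated correlation). So were 9 of 51 RNA-binding and translation factors (median -0.21, adjusted p = 6e-07, and adjusted p = 0.194 with an estimated correlation). Cell cycle genes gave 10 lower of 45 (median -0.20, adjusted p = 7.89e-05, and adjusted p = 0.175 with an estimated correlation). Also lower were 3 of 10 reported Dazl-bound transcripts (median -0.26, adjusted p = 0.00727, and adjusted p = 0.429 with an estimated correlation), namely Tex19 (-0.43 ± 0.086), Cdc25a (-0.44 ± 0.076) and Sdad1 (-0.51 ± 0.094, with 1 of 2 probes of opposite sign). Ddx4 (0.011 ± 0.15), Sycp3 (-0.21 ± 0.20), Crisp2 (0.45 ± 0.20), Tbpl1 (-0.27 ± 0.089), Grsf1 (-0.25 ± 0.092) and Cdc25c (0.13 ± 0.085) did not pass. Pluripotency genes (5 lower of 23, median -0.25, adjusted p = 0.000783), Polycomb genes (6 of 32, median -0.11, adjusted p = 0.00902) and endoplasmic reticulum genes (8 of 36, median -0.099, adjusted p = 0.000783) were lower as lists, with adjusted p = 0.185, 0.175 and 0.429 with an estimated correlation. Adjusted over the list alone, 13 spermatogonial, 19 RNA-binding, 15 cell cycle, 5 Dazl-bound, 8 pluripotency, 6 Polycomb and 9 endoplasmic reticulum genes were lower.

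Higher with V5 were 7 of 21 Sertoli markers (median 0.29, adjusted p = 0.000317, and adjusted p = 0.175 with an estimated correlation), and 13 adjusted over the list alone. Myoid (3 of 15, median 0.23, adjusted p = 0.0205), leukocyte (2 of 19, median 0.23, adjusted p = 0.0106) and late spermatocyte and spermatid genes (4 of 22, median 0.15, adjusted p = 0.0256) were higher as lists, with adjusted p = 0.483, 0.474 and 0.483 with an estimated correlation, and 5, 6 and 5 genes adjusted over the list alone. Endothelial markers were higher as a list (median 0.23, adjusted p = 0.0205, and adjusted p = 0.483 with an estimated correlation), of which limma called 0 over all genes and 4 adjusted over the list alone, with 7 at an unadjusted p under 0.05. Ribosomal protein genes (median 0.16, adjusted p = 0.000783), oxidative phosphorylation genes (0.20, adjusted p = 0.000282) and proteasome genes (0.15, adjusted p = 0.0316) were higher as lists, with adjusted p = 0.569, 0.483 and 0.483 with an estimated correlation. Among them 3, 3 and 5 genes were higher and 1, 3 and 1 lower. Adjusted over the list alone, 2 and 7 oxidative phosphorylation and proteasome genes were higher and 3 and 2 lower, and limma called 0 ribosomal protein genes, with 22 at an unadjusted p under 0.05. The proteasome list no longer passed without V5 replicate 1, GFP replicate 1 or GFP replicate 2 (0.16, 0.18 and 0.13). The late spermatocyte and spermatid list no longer passed without V5 replicate 1 or GFP replicate 2 (0.13 and 0.14), nor the myoid, leukocyte or endothelial list without V5 replicate 2 (0.17, 0.24 and 0.23) or GFP replicate 1 (0.21, 0.19 and 0.20). Leydig markers passed without V5 replicate 1 (0.22) or GFP replicate 2 (0.23). With spike-in scaling the medians of the lists that passed kept their sign, and the proteasome list no longer passed (0.045, adjusted p = 0.103). Meiotic prophase, piRNA pathway, apoptosis, histone, Leydig and erythroid lists did not pass, with adjusted p from 0.102 to 0.683. For the first 3 camera's direction was downward, at medians that were positive but lay below that of all genes. The largest differences among genes measured with both antibodies were upward Sult1c1 (1.36 ± 0.33) and Ifnab (1.30 ± 0.29), each above background on 1 of 2 GFP arrays, and downward Kiss1r (-1.09 ± 0.16), Plekhb2 (-0.91 ± 0.068) and Aebp2 (-0.84 ± 0.21). Measured with 1 antibody alone, and so without rank, were Olfr578 (at least 1.99-fold higher), Adora3 (at least 1.44-fold), Olfr1055 (at least 1.32-fold), Rab37 (at least 1.44-fold lower) and Olfr434 (at least 1.41-fold). By limma 1195 genes were higher, 51 of them at least 2-fold, and 1264 lower, 12 of them at least 2-fold, around a median of 0.089 over all genes. With spike-in scaling that median was -0.018 and 10.6% of calls were higher in place of 48.6%. With normexp background correction limma called 0 genes, with 800 at an unadjusted p under 0.05. With local background subtracted and an offset of 50 in its place, limma called 3772. It called 4 with no filter on background, 2 with only the groups compared and 794 with the replicate block. Calls rose to 3865 with only probes above background on all arrays and to 4568 with trend and robust. The 2459 calls fell to 5 without V5 replicate 1, 7 without V5 replicate 2, 145 without GFP replicate 1 and 19 without GFP replicate 2, while 6730 genes had an unadjusted p under 0.05. Each gene named as higher or lower in this comparison lost its call without V5 replicate 1, V5 replicate 2 or GFP replicate 2, and without GFP replicate 1 the calls of Olfr578, Ifnab, Plekhb2 and Aebp2 alone remained. When both arrays of conflicting descriptions were left out, 4 genes were called, not 1 of them named here, the late spermatocyte and spermatid list and the proteasome list did not pass (0.13 and 0.16), and Leydig markers did.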

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

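The test of the slide, the correlations of the IgG arrays' difference with GFP minus V5, and the tests of what the mock lost of spermatogonial and Sertoli genes were chosen after their results were seen. The V5 and GFP precipitates differed from each other in 15 gene lists by limma's camera test, though in 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. V5 minus GFP, the median log2 difference was -0.406 for spermatogonia, -0.261 for reported Dazl-bound transcripts, -0.246 for pluripotency, -0.211 for RNA-binding and translation factors, -0.198 for the cell cycle, -0.111 for Polycomb and -0.099 for endoplasmic reticulum genes. It was 0.148 for late spermatocyte and spermatid genes, 0.152 for the proteasome, 0.161 for ribosomal proteins and 0.199 for oxidative phosphorylation. Among markers of other cells it was 0.226 for myoid, 0.229 for endothelial, 0.231 for leukocyte and 0.286 for Sertoli markers.

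These differences run along the difference of both precipitates from IgG, in which late spermatocyte and spermatid genes had medians below 0 like the somatic markers. GFP minus V5 correlated with the mean of both minus IgG at r = 0.606 across genes, which are not independent replicates, and at 0.285 to 0.894 within each of 10 bins of input signal. V5 and GFP arrays share a slide, and both enter both axes. The r restates that fold changes against IgG spread wider with GFP (SD 0.719) than with V5 (SD 0.535). A slide difference of equal size on all its arrays would not give this, but a slide difference of unequal size would. The test therefore does not decide whether the slide is the cause. How much the slide adds cannot be told apart from the groups. A technical gradient that parts arrays within a slide is not excluded. The difference between the IgG arrays, which share a slide, correlated with GFP minus V5 at r = 0.85 over the medians of 19 autosomes and at 0.115 across genes, and with both precipitates minus input at -0.916 over the autosomes. If the precipitates only undid what the mock lost, the mock would have lost spermatogonial genes by at least 0.419, where their shift against all genes was 0.838. IgG minus input over that list lay at 0.071 ± 0.172 against all genes, not at such a loss. That SE treats the list's members as independent, while their estimated correlation was 0.137. The SE may therefore be too small, so the value does not decide the question. For Sertoli markers, shifted by -0.237, the value was -0.301 ± 0.221. The mock thus moved them downward, where a reversal needs upward, but the spread is too wide to decide. After the trend on IgG minus input was removed, -0.243 ± 0.059 or 103% of the shift was left. Removing the trend cannot shrink a list that the mock moved the same way, so this does not decide it either.

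For reported Dazl-bound transcripts, which the mock had lost (-1.02 ± 0.689 against all genes), 82.2% of the shift was left after the trend on IgG minus input was removed (0.85 ± 0.21, of 1.03 before), too wide a spread over 10 genes to decide. Binding to the tagged protein remains an untested explanation, since no group of the design lacks the tag.

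Spike-in probes, which the comparisons use only under spike-in scaling, lay further above the 75th percentile in each precipitate than in the input. The log2 difference from input was 0.789 with IgG, 0.425 with V5 and 0.318 with GFP, while the SD between arrays of a group was 0.052 at most. No test decides between less RNA per array and a different make-up of the RNA.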

How the results depend on the processing

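The background subtraction with a fixed offset and the fit without both arrays of conflicting descriptions were chosen after seeing the data. The other alternatives were fixed before the data were examined. Where no cause is named below, the cause was not tested. A slide block gave no value, since each group lies on 1 slide. Scaling to the median of bright probes, the mean of all probes and quantile normalization kept each gene count and overlap within 1.5 times; of the list counts only that of IgG against input left that range, with 10 under quantile normalization and 3 under the median.

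Spike-in scaling, which shifts all genes of an array alike, moved counts from one direction to the other. Higher and lower were 6250 and 914 for V5 against IgG, 6844 and 2202 for GFP against IgG, 2411 and 10917 for IgG against input, 3520 and 9628 for V5 against input, and 227 and 1921 for V5 against GFP. Higher for GFP against input were 4163, and the antibodies' overlap was 5723. Signs reversed for Pabpc1 (0.113), Gas5 (0.07) and H19 (0.081) with GFP against IgG, and for Cdc25a with IgG (-0.391) and V5 (-0.083) against input. Averaging all probes reversed Sdad1 against input with V5 (-0.762) and GFP (-0.6).

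With normexp limma called 0 genes for V5 against IgG, 0 higher and 0 lower (3688 at an unadjusted p under 0.05), and 0 for V5 against GFP, 0 higher and 0 lower (800 at an unadjusted p under 0.05). The overlap was then 0 and 0 genes stood above both controls with V5, 862 with GFP. Other counts were 3219 for GFP against IgG (1500 higher, 1719 lower), 6272 for IgG against input (3859 and 2413, with 10 lists), 5250 for V5 against input (2968 and 2282) and 5697 for GFP against input (3191 and 2506). The antibodies' correlation was 0.9474, and Cdc25c reversed for V5 against input (0.029). The default fit placed the background at -391 on V5 replicate 2 and -333 on GFP replicate 2, against -92.5 to -10.9 elsewhere. The lowest spots of V5 replicate 2 and GFP replicate 2 lay at -18600 and -13520, and whether they set the fit was not tested. With local background subtracted and an offset of 50 the gene counts stayed within 1.5 times except for V5 against GFP, which gave 3772 (1835 and 1937), with 8 lists for IgG against input and a correlation of 0.9455.

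V5 against GFP depended most on the settings. It gave 4 genes with no filter on background (2 higher, 2 lower), where 8 lists passed for IgG against input and the antibodies correlated at 0.8233. It gave 3865 with only bright probes (2095 higher, correlation 0.9499), 4568 with trend and robust (2572 and 1996), 794 with the replicate block (251 and 543), and 2 with only the groups compared (2 higher, and 0 lower by limma, with 7343 at an unadjusted p under 0.05). Replicate deviations of any pair of groups correlated between -0.075 and 0.107. Arrays of the same replicate number thus showed no strong shared deviation, which does not exclude that the numbers pair arrays. With estimated correlations 0 lists passed camera in each of the 6 comparisons.

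Leaving out each array assumes that a lone array varies like the other groups. The counts then ranged from 6035 to 10629 for V5 against IgG (1927 to 3334 higher, 4108 to 7295 lower), 1886 to 3102 for the overlap, 0.8936 to 0.9316 for the correlation, 999 to 1520 for genes above both controls with V5, 3 to 5 for the lists of IgG against input, and 5 to 145 for V5 against GFP (3 to 110 higher, 2 to 35 lower). Without both arrays of conflicting descriptions V5 against IgG gave 1249 (657 and 592), the overlap 647, the correlation 0.8974, V5 above both controls 389, IgG against input 3 lists, and V5 against GFP 4 (3 and 1), and 46 calls of named genes and 5 of lists ended, as given with each comparison. Fewer arrays leave fewer degrees of freedom.

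The authors' means gave log2 ratios that ranked 9886 matched genes like those here, with Spearman rho of 0.999 for V5 and 0.998 for GFP against input and 0.976 for V5 against GFP. Pearson r was lower, at 0.9135, 0.9064 and 0.622, with median differences of 0.27, 0.29 and -0.023. Of calls, 97.9%, 97.1% and 100% had the same sign. Of the named genes' values 34 moved by more than the spread between replicates and 18 did not, with 0 reversed. Calls of named genes that ended numbered 108 with normexp, 26 with no filter on background, 24 with only the groups compared, 14 with spike-in scaling, 11 with the replicate block, 4 with quantile normalization, 3 with the mean of all probes and 1 with the fixed offset.

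Lists that passed and no longer did numbered 9 with spike-in scaling: ribosomal proteins (0.115 and 0.077) and oxidative phosphorylation (0.077 and -0.003) for V5 and GFP against IgG, Sertoli markers for V5 against IgG (0.017), Dazl-bound transcripts for IgG against input (-1.592), myoid markers for V5 and GFP against input (-1.348 and -1.438) and the proteasome for V5 against GFP. With normexp they numbered 7: meiotic prophase (0.099), piRNA pathway (0.01) and endoplasmic reticulum (-0.048) for V5 against IgG, late spermatocyte and spermatid genes for GFP against IgG (-0.307) and V5 against input (-0.02), Polycomb for V5 against input (0.557) and the proteasome for V5 against GFP (0.141). Another 3 were lost with the median of bright probes, 3 with the mean of all probes, 2 with only bright probes, 1 with quantile normalization and 1 with the fixed offset. Lists that newly passed numbered 14 with normexp, 10 with no filter, 8 with spike-in scaling, 8 with the fixed offset, 6 with quantile normalization, 6 with the mean of all probes, 2 with only bright probes and 2 with only the groups compared. Dim probes limit what can be seen: 57.2% to 62.3% of spots lay well above background.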

Other observations

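The tests of the background filter, of olfactory receptor probes above background and of the X chromosome's rank were chosen after their results were seen, as was the choice of the olfactory and X-linked patterns; the other tests below were written down before their results. Olfactory receptor genes were among those named as lower than with IgG. Over all 951 olfactory receptor probes, unfiltered, the median of both precipitates minus IgG was -0.266, against -0.212 over all probes, so whether the filter's choice of probes makes the pattern cannot be told apart from a shift of all probes. Other probes of equal signal had a median of -0.218 (95% of 1000 draws from -0.236 to -0.206), from which the olfactory probes differed by -0.048. That pooled value mixes unlike parts: in the 3 dimmest of 10 bins of signal olfactory and other probes had like medians (-0.264 and -0.26 in bin 3), while in bins 4, 5 and 6 olfactory probes lay at -0.983, -0.894 and -0.913 and others at -0.427, -0.37 and -0.244. It therefore does not decide whether dim probes in general make the pattern. Of the olfactory probes 68 lay well above background on all 8 arrays, with a median of -0.757. This differed by -0.45 from other such probes of equal signal (-0.307, 95% of draws from -0.429 to -0.179), which argues against a lower signal of dim probes in general for these 68. No other cause was tested. The share of these probes well above background was 19.7% and 21% on the input arrays, 24% on IgG replicate 2 and below both input arrays on IgG replicate 1, 16.4% and 12.4% with V5, and 16.6% and 10.3% with GFP.

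Several of the transcripts furthest above IgG are X-linked, as Nxt2, Hccs, Cetn2, Taf9b and Vbp1. That X-linked transcripts as a class were recovered above autosomal ones was not decided: the medians of both precipitates minus IgG were -0.083 for the X chromosome and -0.080 for chromosome 18, the 1 autosome above it, a gap within the SE of 0.038 and 0.042. The autosome medians followed IgG minus input (r = -0.934 over 19 autosomes and 14031 placed genes, and -0.925 and -0.923 with the IgG arrays split between the axes), and the X chromosome lay -2.97 SD off that line, at -0.083 where the line gives 0.017. This was written down as counting against the trend, but it does not: the X chromosome lies below the line, and its IgG minus input of -0.383 is beyond the lowest autosome's -0.212. Whether the trend raises the X-linked transcripts therefore remains undecided. Splitting the IgG arrays takes the noise of single arrays out of the trend's r. A deviation common to both IgG arrays would still make it negative. The same trend parts the IgG arrays from each other, with r = -0.916 between the autosome medians of IgG replicate 1 minus replicate 2 and of both precipitates minus input (permutation p = 1e-05, the smallest that 100000 draws can give). A technical gradient may therefore lie behind the differences between chromosomes.

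The 3 precipitates resembled each other more than the input. With the input arrays split between the axes, IgG minus input correlated across genes, which are not independent replicates, with V5 minus input at r = 0.813 and 0.835, and with GFP minus input at 0.711 and 0.736. With the IgG arrays split, the precipitates minus IgG correlated with IgG minus input at -0.257 and -0.309. A deviation common to both IgG arrays would also give negative values here.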
